A study of Arabidopsis thaliana with 4 samples.

How the data were processed

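Whole seedling RNA-seq libraries of Arabidopsis thaliana were compared, 2 of Col-0 and 2 of lux-6, grouped by the genotype and title in the labels. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I and made into libraries with an NEBNext Ultra RNA kit, and the labels do not say whether strand was kept. The submitters' processing notes name TopHat2 2.0.12 and TAIR10 without saying what each was used for. The counter, the gene lengths, any filter and the total behind the scaling are not given in the sources used here. The deposited values are FPKM per the file headers, 1 library per file, for the same 33602 gene IDs, of which 9070 were at 0 in all libraries. Gene names and product names came from the RefSeq annotation of TAIR10.1, which had an entry for 97.7% of the IDs. Its exon coordinates were used only for the annotated gene lengths. The notes name another release, so genes are given by their AGI identifiers and not by position.

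FPKM values are not counts, so the test planned for counts was replaced by the one planned for normalized values. Limma 3.58.1 in R 4.3.3 was fitted with a mean-variance trend to log2(FPKM + 1), with genotype as its only term, on 19592 genes with a mean of at least 1 FPKM over the 4 libraries. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene is from this model over all genes, unless another fit or a list alone is named. Fold changes are lux-6 against Col-0 on that scale, which understates the change of genes with low values. With 2 libraries per genotype an exact permutation test cannot give a two-sided p under 0.333. The residual degrees of freedom were 2 and the prior degrees of freedom of the model 2.88.

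Depth was worked back from the values. FPKM was taken to be a whole number of fragments divided by a gene length and a library total, which was checked by a search. The search over lengths between 0.5 and 1.2 times the annotated one gave whole fragments, within 0.002, for 20312 of 24532 genes above 0, or 82.8%. The share was 97.9% for genes with 1 annotated transcript and 64.9% for genes with several. For the remaining genes fragments were estimated from the annotated length. The estimates summed to between 104.8% and 107.6% of the recovered library totals. On simulated values the search returned the true fragments for 99.8% of 23897 genes and all 4 totals exactly. Fragments were used for replicate scatter, a stricter filter and the limma-voom alternative. Plastid and mitochondrial genes were 279 of the IDs.

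Before the data were examined, 25 gene lists, 20 families from product names, the alternatives and the rule for named genes were fixed. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over lists and over families separately. Camera called 14 of 25 lists and 11 of 20 families. With a correlation estimated for each set it called 0 of either, where 2 residual degrees of freedom stand behind each estimate. Fry, which does not compare a list with other genes, gave no list an adjusted p at most 0.05 for movement in one direction (smallest 0.128) and 8 lists for change in either direction (smallest 0.0239). Counts of members are given over all genes and adjusted over the list alone.

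The text names LUX, MYC2 and the members of the evening complex and target lists. It names the 8 genes with the largest change in each direction among those past the test with a mean of at least 5 FPKM and both genotypes apart. It names up to 4 members past the test of each list, or the 2 with the smallest p where none passed, and members of reference, organ and stress lists needed to describe the libraries. Other genes were chosen after their values were seen. These are LHY, CCA1, SAG12 and the Rubisco genes, and further ones for which this is said where they appear.

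The model was tested on simulated values of lux-6 against Col-0. With 19550 genes tested and the spread of the lux-6 libraries given to both genotypes, it recovered 90% of 2-fold and 100% of 4-fold, 8-fold and 16-fold changes, with 18 false calls. With 19570 genes tested and each genotype's own spread it recovered 2.08% of 2-fold, 85.7% of 4-fold, 89.8% of 8-fold and 100% of 16-fold changes, with 0 false calls. In the simulation, changes of 2-fold were thus mostly out of reach at the spread of the Col-0 libraries. In the measured values, Col-0 replicate 1 minus 2 correlated with lux-6 minus Col-0 at r = 0.654 across genes. Both differences contain the same Col-0 libraries, so a wider spread of Col-0 replicate 2 than of replicate 1 alone gives a positive r. The simulation gave the Col-0 libraries a common spread. The simulated rates of recovery and of false calls may therefore not hold for the measured values.

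Alternatives were median-of-ratios scaling, other filters, a pseudocount of 0.1, a replicate block, removal of organelle genes and each library left out. After the data were seen, limma-voom on fragments, limma array weights, removal of seed transcripts and 4 further gene lists were added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for reading the files, the search for fragments and the plots.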

Results

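Messenger RNA of whole Arabidopsis thaliana seedlings was measured in the wild type Col-0 and in the lux-6 mutant, with 2 libraries of each genotype that the series describes as biological replicates. LUX encodes a transcription factor of the evening complex, which it forms with ELF3 and ELF4 and which represses its targets around dusk. Seedlings were 10 days old, had grown in long days at 22 °C on medium with 3% sucrose, and were collected 12 h after lights on (zeitgeber time 12), when components of the complex are near their daily maximum. Expression is given as FPKM, fragments scaled by gene length and library depth. The totals behind the scaling, worked back from the values, were 11019616 and 11198704 fragments for Col-0 replicates 1 and 2, and 10969717 and 10735709 for lux-6 replicates 1 and 2. The comparison asks which transcripts differ when LUX is affected, in a series concerned with leaf senescence.

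The LUX transcript (AT3G46640) stood at 57.0 and 73.9 FPKM in Col-0 replicates 1 and 2 and at 34.8 and 35.3 FPKM in lux-6 replicates 1 and 2. The means were 65.5 ± 11.9 and 35.0 ± 0.345 FPKM (SD, n = 2), a log2 fold change of -0.87 with a standard error of 0.19. The difference did not pass the limma test over all genes (adjusted p = 0.187), and the labels do not say what kind of lesion lux-6 is. The log2 fold change was -0.69 without Col-0 replicate 2 and -1.06 without Col-0 replicate 1. Such fits leave 1 Col-0 library and take their spread from the lux-6 pair, so calls made with them are not stronger evidence. Of the partners, ELF3 (AT2G25930) was at 52.1 and 54.4 FPKM in Col-0 and at 48.2 and 52.5 in lux-6, and ELF4 (AT2G40080) averaged 149 ± 0.154 and 131 ± 14.7 (SD, n = 2). BOA (AT5G59570), a homologue of LUX, was at 20.6 ± 4.80 FPKM in Col-0 and 35.8 ± 2.48 in lux-6. None of the 4 evening complex genes passed over all genes. Adjusted over the list alone, BOA passed upwards and LUX downwards, with adjusted p = 0.0314 and 0.0260. As a list, the evening complex was not called (camera adjusted p = 0.397).

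Published targets of the evening complex lay higher in lux-6. PIF5 (AT3G59060), a growth-promoting transcription factor, averaged 17.4 ± 15.3 FPKM in Col-0 and 121 ± 3.91 in lux-6, and PIF4 (AT2G43010) 23.4 ± 23.3 and 89.3 ± 4.81 (SD, n = 2). The clock genes PRR7 (AT5G02810), GI (AT1G22770) and LNK1 (AT5G64170) had log2 fold changes of 1.34, 0.98 and 1.31, and of 0.95, 0.65 and 0.93 without Col-0 replicate 2. TOC1 (AT5G61380) had 0.26, and PRR9 (AT2G46790) was left untested because its mean was under 1 FPKM, with 0.372 ± 0.248 FPKM in Col-0 and 1.09 ± 0.124 in lux-6. Of the 8 tested targets, 7 were higher in both lux-6 libraries than in both Col-0 libraries and 1, LUX itself, was lower. None passed over all genes, while 6 passed upwards and 1 downwards when adjusted over the list alone. The median log2 fold change was 1.15 and the list was called higher (camera adjusted p = 0.00308), which was lost at adjusted p = 0.563 with an estimated correlation. In Col-0 the same genes differed between replicates, with a median of -0.71 in replicate 2 relative to replicate 1. PIF4 stood at 39.9 and 6.98 FPKM in these libraries and PIF5 at 28.2 and 6.61. Without Col-0 replicate 2 the median was 0.79.

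**Figure D1:**
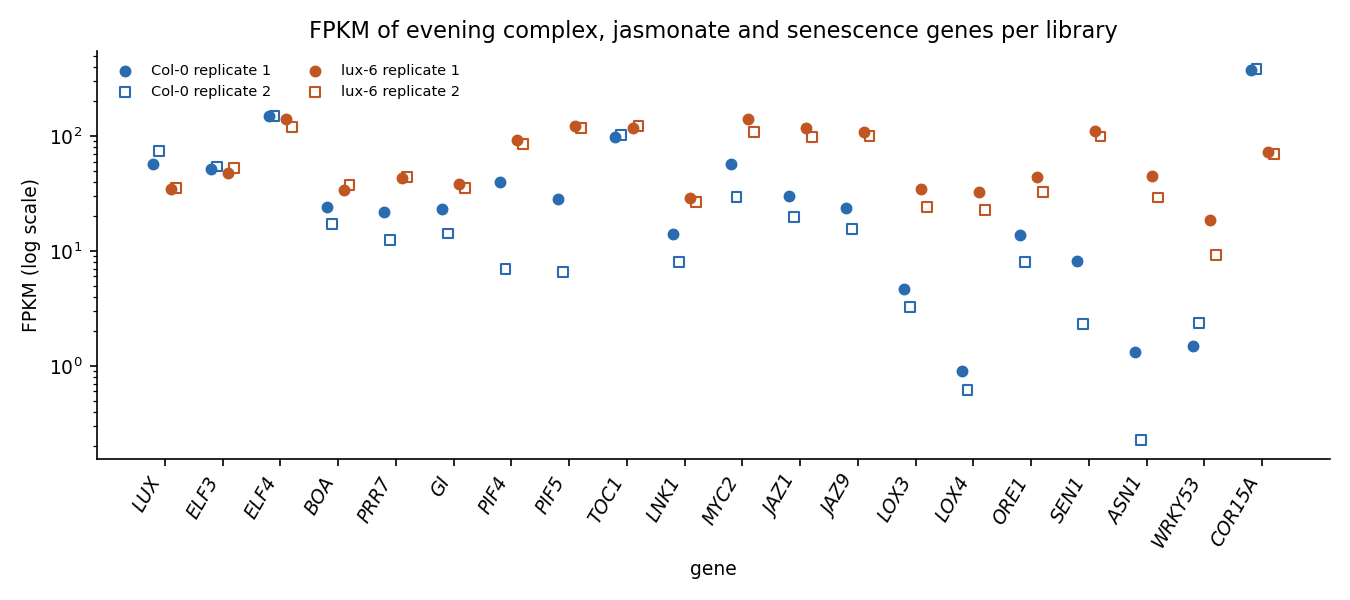
FPKM on a log scale of 20 genes in each of the 4 libraries, with Col-0 in blue, lux-6 in orange, circles for replicate 1 and open squares for replicate 2. Both lux-6 libraries lie above both Col-0 libraries for PIF4, PIF5, MYC2 and LOX4, and below them for LUX and COR15A.

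Across 19592 tested genes, 56 rose and 1 fell in lux-6 (limma, adjusted p at most 0.05). The seed storage albumin gene SESA3 (AT4G27160) rose from 0.294 ± 0.252 FPKM in Col-0 to 159 ± 29.2 in lux-6, and SESA4 (AT4G27170) from 0.264 ± 0.373 to 56.6 ± 0.768 (SD, n = 2). Their log2 fold changes on the log2(FPKM + 1) scale were 6.95 and 5.54, with adjusted p = 0.0234 and 0.0330. They rest on 4 and 1 fragments of SESA3 and 4 and 0 of SESA4 in Col-0, which leaves the size of the change imprecise. The seed storage genes CRU2 (AT1G03880) and SESA5 (AT5G54740) rose by 5.02 and 4.62. The cysteine-rich peptide gene LCR67 (AT1G75830) and the thionin gene AT2G15010 rose by 4.81 and 4.54. ASN1 (AT3G47340), which encodes an asparagine synthetase induced by carbon shortage and in senescing leaves, rose from 0.773 ± 0.775 to 37.1 ± 11.1 FPKM (SD, n = 2). CML38 (AT1G76650), a calmodulin-like gene, rose from 1.60 ± 0.788 to 47.0 ± 5.53 FPKM. With limma-voom on fragments, added after the data were seen, SESA3, CML38 and COR15A passed. SESA4, CRU2, SESA5, LCR67, AT2G15010 and ASN1 did not, with adjusted p = 0.0636, 0.0916, 0.0635, 0.0956, 0.0506 and 0.0636. The gene that fell was COR15A (AT2G42540), which encodes a chloroplast protein of cold acclimation. It stood at 373 and 381 FPKM in Col-0 and at 72.1 and 69.6 FPKM in lux-6, a log2 fold change of -2.40 (adjusted p = 0.0330).

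These counts rested on the libraries in the fit. A fit that leaves 1 library of a genotype takes its spread from the pair of the other, so larger counts there are not stronger evidence. Without Col-0 replicate 2, 680 genes were higher and 70 lower, and without Col-0 replicate 1, 4244 were higher and 2374 lower. Without lux-6 replicate 1 or without lux-6 replicate 2 no gene passed in limma, with 874 and 889 genes at an unadjusted p under 0.05 against 2407 in the full fit. All 57 genes were shared with the calls made without Col-0 replicate 2. Limma-voom called 78 genes, 44 of them among the 57. In lists without a member past the test, it called 1 member each of the morning-phased clock, jasmonate signalling, and heat and handling lists. At an unadjusted p under 0.05 limma had 7 of 8 evening complex targets, 7 of 10 morning-phased clock genes, 11 of 18 PIF and shade growth genes, 7 of 15 auxin genes, 15 of 26 jasmonate signalling genes and 7 of 17 flavonoid genes. It had 0 of 8 chlorophyll breakdown genes, 2 of 13 abscisic acid genes and 0 of 9 reference genes. Both lux-6 libraries lay above both Col-0 libraries for 5106 genes and below them for 4458, together 48.8% of genes. For 2 against 2 exchangeable libraries the share by chance is 33.3%. These libraries were not exchangeable, since the lux-6 pair lay close together and Col-0 replicate 2 stood apart. The excess over 33.3% is therefore no measure of a genotype effect.

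Col-0 replicate 2 stood apart from the other libraries. The labels give no difference from Col-0 replicate 1 beyond the replicate number. The values leave its identity and preparation in doubt, and each Col-0 mean and SD includes it. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.909 between the Col-0 libraries and 0.984 between the lux-6 libraries. Col-0 replicate 1 correlated with lux-6 replicates 1 and 2 at 0.955 and 0.957, and Col-0 replicate 2 at 0.863 with each. Plastid-encoded transcripts made up 3.09% of the FPKM total in Col-0 replicate 2 and 0.0525% in Col-0 replicate 1, against 0.0698% and 0.0530% in lux-6 replicates 1 and 2. The Rubisco small subunit gene RBCS1A (AT1G67090) was at 20766 FPKM in Col-0 replicate 2 and at 10599, 8714 and 8630 FPKM in the others.

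**Figure D2:**
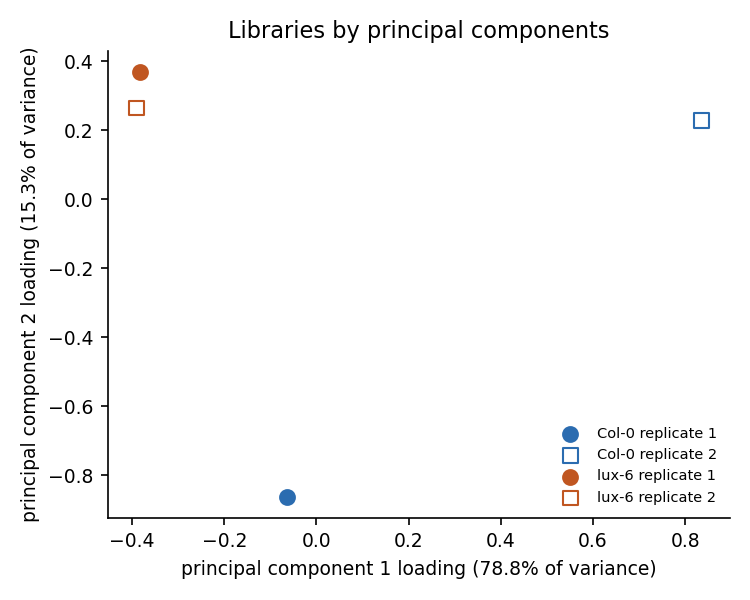
Position of the 4 libraries on the first and second principal components of log2(FPKM + 1), with the share of variance on each axis. Col-0 replicate 2 lies at 0.835 on the first component, which holds 78.8% of the variance, and the other 3 libraries lie between -0.390 and -0.0630.

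Jasmonate signalling and response transcripts were higher in lux-6 as a list. MYC2 (AT1G32640), a transcription factor at the centre of jasmonate signalling, averaged 43.3 ± 19.5 FPKM in Col-0 and 124 ± 23.0 in lux-6 (SD, n = 2). The repressor genes JAZ9 (AT1G70700) and JAZ1 (AT1G19180), which jasmonate itself induces, averaged 19.5 ± 5.63 and 24.8 ± 7.18 FPKM in Col-0 and 104 ± 6.66 and 108 ± 14.6 in lux-6. Of 26 tested members none passed over all genes, where MYC2, JAZ9 and JAZ1 had adjusted p = 0.197, 0.0525 and 0.0658. Adjusted over the list alone, 13 passed and all 13 were higher. The median log2 fold change was 1.36 (camera adjusted p = 6.94e-09; adjusted p = 0.563 with an estimated correlation). The median difference of Col-0 replicate 2 from replicate 1 was -0.53, and without Col-0 replicate 2 the median fold change was 0.91.

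Among jasmonate biosynthesis genes the lipoxygenase gene LOX4 (AT1G72520) rose, from 0.756 ± 0.197 FPKM in Col-0 to 27.8 ± 7.07 in lux-6 (SD, n = 2; log2 fold change 4.02, adjusted p = 0.0330). Its values rested on 30 and 21 fragments in Col-0 and 1095 and 745 in lux-6. The other 13 tested members did not pass over all genes, and 6 of the 14 passed upwards when adjusted over the list alone. LOX2 (AT3G45140) and AOC2 (AT3G25770), named after their values were seen, were at 228 ± 21.4 and 328 ± 82.3 FPKM in Col-0 and 197 ± 17.7 and 294 ± 18.3 in lux-6. AOC2 was lower in Col-0 replicate 2 (270.1 FPKM) than in both lux-6 libraries (307 and 281 FPKM), so its direction turns without Col-0 replicate 1. The list was called higher with a median of 0.71 (camera adjusted p = 0.000267; adjusted p = 0.563 with an estimated correlation). Its median differed by -0.41 between Col-0 replicate 2 and replicate 1, and without Col-0 replicate 2 it was 0.38.

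Leaf senescence transcripts were higher in lux-6 as a list, with a median log2 fold change of 1.44 over 23 tested members. ASN1 rose over all genes, though not with limma-voom (adjusted p = 0.0636), and the other 22 did not pass. Adjusted over the list alone, 13 passed, all higher, and 19 members were higher in both lux-6 libraries than in both Col-0 libraries. ORE1 (AT5G39610) and WRKY53 (AT4G23810), transcription factors that promote leaf senescence, and SEN1 (AT4G35770) were named after their values were seen. ORE1 was at 13.9 and 7.97 FPKM in Col-0 and at 43.9 and 32.4 in lux-6. WRKY53 averaged 1.93 ± 0.609 and 14.0 ± 6.72, and SEN1 5.22 ± 4.13 and 105 ± 7.94 (SD, n = 2). The late marker SAG12 (AT5G45890) was listed at 0 in all 4 libraries. Camera called the list higher (adjusted p = 2.70e-11; adjusted p = 0.563 with an estimated correlation). The median difference of Col-0 replicate 2 from replicate 1 was -0.47, and without Col-0 replicate 2 the median was 1.15.

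Chlorophyll breakdown genes were not called (camera adjusted p = 0.728), and no member passed over all genes or over the list alone. NYE1 (AT4G22920), which encodes the magnesium dechelatase that opens chlorophyll breakdown, averaged 8.55 ± 1.31 FPKM in Col-0 and 11.7 ± 3.74 in lux-6, and PPH (AT5G13800) 23.1 ± 5.79 and 30.9 ± 2.06 (SD, n = 2). The list's median was 0.06 and turned to -0.15 without Col-0 replicate 2, and the direction of the test turned there (adjusted p = 0.462) and without lux-6 replicate 1 (adjusted p = 0.716). Chlorophyll synthesis genes were not called either (camera adjusted p = 0.350). Their median was -0.13 and their mean 0.05, with DVR (AT5G18660) at -0.91 and HEMA1 (AT1G58290) at 1.58 on the log2 scale. Without Col-0 replicate 2 the median was -0.24 and HEMA1 stood at 0.93, and the direction of the test turned without lux-6 replicate 2 (adjusted p = 0.906).

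Light-harvesting antenna and Rubisco small subunit genes were called higher as a list, with a median of 0.47 over 23 members (camera adjusted p = 0.00883; adjusted p = 0.598 with an estimated correlation). LHCB1.1 (AT1G29920) rose from 39.8 ± 0.466 to 300.0 ± 50.9 FPKM (SD, n = 2; adjusted p = 0.0330). Reads shared with near-identical LHCB1 copies could make this value uncertain, which was not tested. Adjusted over the list alone 2 members passed, both higher. The Rubisco small subunit genes lay on the other side, with log2 fold changes of -0.77 for RBCS1A and -1.36 for RBCS2B (AT5G38420), named after their values were seen, and neither passed over all genes. The values were -0.29 and -1.12 without Col-0 replicate 2. The list's median differed by -0.51 between Col-0 replicate 2 and replicate 1, and without Col-0 replicate 2 it was 0.44.

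Growth genes linked to light and auxin were higher in lux-6 as lists. The growth and auxin lists share IAA19, IAA29, YUC8 and SAUR19, and PIF4 and PIF5 are also in the target list. Every other tested target is also in a clock list. WRKY70, EIN3 and SAG113 of the senescence list are also in the salicylic acid, ethylene and abscisic acid lists, and ERF1 is in the jasmonate signalling and ethylene lists. The calls of lists that share members are therefore not separate results. Of 18 PIF and shade growth genes none passed over all genes and 8 passed upwards when adjusted over the list alone. HAT2 (AT5G47370) was at 23.5 and 19.5 FPKM in Col-0 and at 51.8 and 50.1 in lux-6, and PAR1 (AT2G42870) averaged 5.82 ± 0.0664 and 13.5 ± 1.06 (SD, n = 2). The median was 0.93 (camera adjusted p = 3.22e-07; adjusted p = 0.563 with an estimated correlation). Of 15 auxin genes none passed over all genes and 7 passed upwards over the list alone. The auxin-inducible genes DFL1 (AT5G54510) and IAA2 (AT3G23030) averaged 16.8 ± 3.66 and 51.3 ± 17.8 FPKM in Col-0 and 49.1 ± 1.04 and 178 ± 21.5 in lux-6. The mean log2 fold change was 1.07 (camera adjusted p = 1.89e-05; adjusted p = 0.563 with an estimated correlation). Between Col-0 replicate 2 and replicate 1 the medians differed by -0.47 for the growth list and -0.67 for the auxin list. Without Col-0 replicate 2 the median fold changes were 0.65 and 0.74.

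Morning-phased clock genes were called higher, with a median of 0.77 over 10 tested members (camera adjusted p = 0.000120; adjusted p = 0.563 with an estimated correlation). RVE1 (AT5G17300) averaged 4.14 ± 0.982 FPKM in Col-0 and 23.0 ± 1.42 in lux-6 (SD, n = 2), and LNK4 (AT5G06980) was at 1.33 and 0.675 FPKM in Col-0 and at 7.86 and 6.87 in lux-6. None passed over all genes and 4 passed upwards over the list alone. CCA1 (AT2G46830) and LHY (AT1G01060), which encode the central morning repressors, were untested with means under 1 FPKM. The list's median differed by -0.46 between Col-0 replicate 2 and replicate 1, and without Col-0 replicate 2 it was 0.51. The afternoon- and evening-phased clock genes had a median of 0.40 and were not called (camera adjusted p = 0.162), except without lux-6 replicate 2 (adjusted p = 0.0315). Over their list alone 4 of 11 passed upwards and 1, LUX, downwards. Photoperiodic flowering genes were not called (camera adjusted p = 0.397), with CDF2 (AT5G39660) at 1.37 and FLC (AT5G10140) at 1.08 on the log2 scale, neither past the test. They stood at 0.89 and 0.76 without Col-0 replicate 2, where the list's median went from 0.31 to -0.16.

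Flavonoid and anthocyanin genes were called lower, with a median of -0.64 over 17 members (camera adjusted p = 4.68e-06; adjusted p = 0.563 with an estimated correlation). MYB12 (AT2G47460), an activator of flavonol synthesis, averaged 8.89 ± 0.819 FPKM in Col-0 and 2.50 ± 0.186 in lux-6 (SD, n = 2). LDOX (AT4G22880), an enzyme of anthocyanin synthesis, had a log2 fold change of -1.16. None passed over all genes, these 2 passed over the list alone, and 12 members were lower in both lux-6 libraries than in both Col-0 libraries. Col-0 replicate 2 lay above replicate 1 by a median of 0.50, and without it the list's median was -0.30.

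Cold response genes went both ways and were not called (camera adjusted p = 0.143), but were called higher without lux-6 replicate 2 (adjusted p = 0.00233) and with a replicate block (adjusted p = 0.0332). COR15A fell and ZAT12 (AT5G59820), a stress-induced zinc finger factor, rose from 3.75 ± 0.355 to 23.9 ± 4.99 FPKM (SD, n = 2; adjusted p = 0.0498). ZAT12 did not pass with limma-voom (adjusted p = 0.0635) or with seed transcripts left out (adjusted p = 0.0535). Adjusted over the list alone, 5 of 14 passed upwards and 2 downwards. Salicylic acid and defence genes were called higher with a median of 0.56 (camera adjusted p = 0.00291; adjusted p = 0.563 with an estimated correlation), and 4 of 8 passed upwards over the list alone. CBP60G (AT5G26920) and WRKY70 (AT3G56400) had log2 fold changes of 1.94 and 2.02, neither past the test over all genes. The median difference of Col-0 replicate 2 from replicate 1 was -0.17 in this list, whose median was 0.38 without Col-0 replicate 2. Its call did not hold without Col-0 replicate 1. Ethylene genes were called higher with a median of 0.38 (camera adjusted p = 0.00847; adjusted p = 0.598 with an estimated correlation). The median difference of Col-0 replicate 2 from replicate 1 was -0.42 in the ethylene list, whose median was 0.30 without Col-0 replicate 2. ACS6 (AT4G11280), an ethylene synthesis gene, passed over the list alone with a log2 fold change of 2.76, and ERF1 (AT3G23240) had 1.34, or 0.83 without Col-0 replicate 2, and did not. Abscisic acid genes had a median of 0.67 (camera adjusted p = 0.00698; adjusted p = 0.599 with an estimated correlation) and no member passed over all genes or over the list alone. Without Col-0 replicate 2, which lay below replicate 1 by a median of 1.22 in this list, their median was 0.06 and the call ended at adjusted p = 0.188. It ended without lux-6 replicate 1 as well (adjusted p = 0.119). ABI5 (AT2G36270) and NCED3 (AT3G14440) had log2 fold changes of 1.41 and 2.11 in the full fit, and NCED3 1.38 without Col-0 replicate 2.

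Starch turnover genes were not called (camera adjusted p = 0.721). Their median was -0.17, or -0.29 without Col-0 replicate 2, and their mean 0.20. BAM5 (AT4G15210), a beta-amylase gene, was at 1.73 ± 0.432 FPKM in Col-0 and 16.8 ± 5.65 in lux-6 (SD, n = 2), the 1 member past the test over the list alone. The direction of the test turned without Col-0 replicate 1 (adjusted p = 0.802) and without lux-6 replicate 2 (adjusted p = 0.740).

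Transcripts of seed storage were called higher in lux-6 as a list. SESA1 (AT4G27140) was at 5.29 and 0.127 FPKM in Col-0 replicates 1 and 2 and at 146 and 116 FPKM in lux-6, and OLEO1 (AT4G25140), an oil body protein gene, at 16.1 and 3.64 and at 80.3 and 91.6 FPKM. All 4 fixed markers passed over the list alone and none over all genes. The median log2 fold change was 4.92 (camera adjusted p = 0.000262; adjusted p = 0.563 with an estimated correlation). Col-0 replicate 2 lay below replicate 1 by a median of 3.07, and without it the list's median was 3.12.

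Markers of tissue composition and handling were read beside these lists. Root markers were not called (camera adjusted p = 0.899), with a median of 0.10 and a mean of -0.09, and their direction turned without Col-0 replicate 2 (adjusted p = 0.230) and without lux-6 replicate 2 (adjusted p = 0.534). IRT1 (AT4G19690), an iron transporter gene of roots, was at 2.27 and 30.9 FPKM in Col-0 and at 0.615 and 0.314 in lux-6. Cell division markers were not called (camera adjusted p = 0.0977). Stomatal lineage markers were called lower (camera adjusted p = 0.0302; adjusted p = 0.563 with an estimated correlation), with a median of -0.21 and MYB60 (AT1G08810), expressed in guard cells, at -1.14. That call ended without Col-0 replicate 2 (median -0.04, adjusted p = 0.298) and without lux-6 replicate 2 (adjusted p = 0.0650). Heat and handling stress genes were not called (camera adjusted p = 0.0755), yet 3 of 9 passed upwards over the list alone. The list was called higher without Col-0 replicate 1 (adjusted p = 0.0426) and without lux-6 replicate 1 (adjusted p = 0.00517). Of these, TCH2 (AT5G37770) and TCH4 (AT5G57560), which touch induces, averaged 35.8 ± 9.71 and 18.6 ± 4.61 FPKM in Col-0 and 209 ± 21.2 and 149 ± 80.2 in lux-6 (SD, n = 2). The 9 reference genes were not called (camera adjusted p = 0.116), with ACT2 (AT3G18780) at 303 ± 7.92 and 285 ± 18.3 FPKM and EF1A (AT5G60390) at 993 and 1888 FPKM in Col-0 and 789 and 816 FPKM in lux-6.

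**Figure D3:**
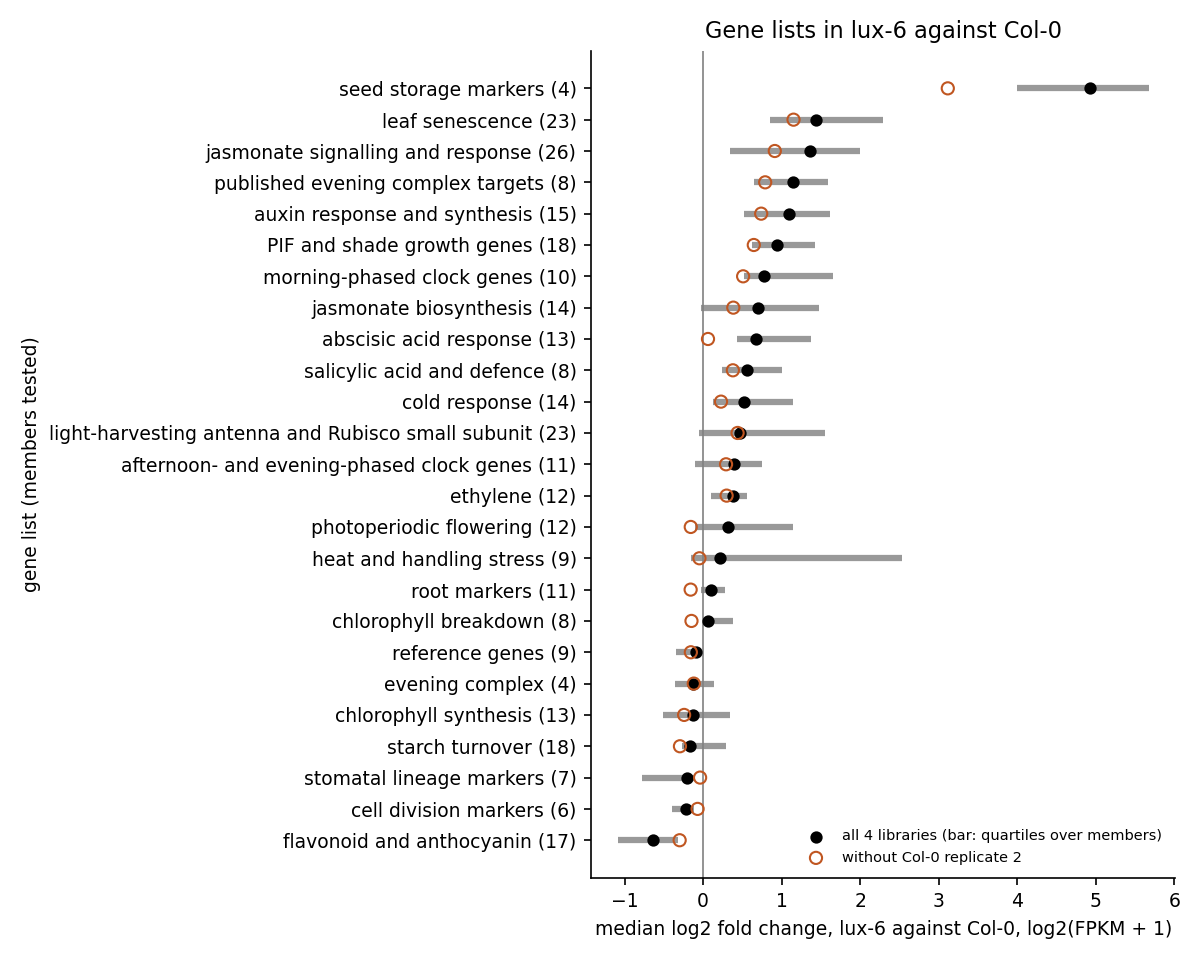
Median log2 fold change of each fixed gene list in lux-6 against Col-0 on the log2(FPKM + 1) scale, with bars for the quartiles over members and open circles for the median without Col-0 replicate 2. Seed storage markers lie at 4.92 and leaf senescence at 1.44, and flavonoid and anthocyanin genes at -0.64. The medians of photoperiodic flowering, heat and handling stress, root and chlorophyll breakdown genes lie below 0 without Col-0 replicate 2.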

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

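Limma-voom on fragments, array weights and the removal of seed transcripts were chosen after the data were seen. Against 56 genes higher and 1 lower, median-of-ratios scaling gave 95 and 1, the stricter filter 101 and 2, removal of organelle genes 128 and 4, array weights 229 and 7, and limma-voom 77 and 1. All 57 genes were shared with each of these except limma-voom, which shared 44. With seed transcripts left out 47 genes were higher and 1 lower, and these 48 were among the 57, of which 52 were still in the fit. That fit left out only members of the seed lists. LCR67, at 0.848 and 0 FPKM in Col-0 and 38.3 and 35.9 in lux-6, stayed in. The 48 may therefore include further seed transcripts. A pseudocount of 0.1 gave 0 and 0 in limma, with 2316 genes at an unadjusted p under 0.05, and no filter gave 0 and 0, with 2680. The cause was not tested. Leaving out 1 library moved the counts between 0 and 4244 higher and between 0 and 2374 lower. There the lone library is assumed to vary like the pair of the other genotype, so the counts follow the narrow lux-6 pair or the wide Col-0 pair. The labels link replicates of the genotypes only by their number. Deviations of same-numbered libraries correlated at -0.0255 across genes. This cannot exclude a shared day, because the Col-0 deviations carry the distance of Col-0 replicate 2 from the other libraries. A replicate block gave 332 genes higher and 8 lower. LUX ranged from -1.06 to -0.69 with 1 library left out. No gene passed without a filter, with the pseudocount of 0.1, without lux-6 replicate 1 (874 at an unadjusted p under 0.05) or without lux-6 replicate 2 (889), so each named gene past the test lost its call there. With limma-voom 7 genes chosen by the naming rule did not pass, namely SESA4, CRU2, SESA5, LCR67, AT2G15010, ASN1 and ZAT12 (adjusted p from 0.0506 to 0.0956), nor did RRTF1 (0.106), named outside the rule, and with seed transcripts left out 1, ZAT12 (0.0535). Genes chosen by that rule kept their direction under the alternatives run. Of those named outside it, AOC2 turns without Col-0 replicate 1.

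With an estimated correlation the 14 list calls ended, at adjusted p = 0.563, 0.598 or 0.599, and the 11 family calls at 0.672. The stomatal call ended with the stricter filter (adjusted p = 0.0566) and limma-voom (0.0535). Heat and handling genes were called with the stricter filter (0.0351), the replicate block (0.0223) and array weights (0.0424), and cold genes with the block (0.0332). Root markers turned lower with the block (0.872) and array weights (0.940), uncalled in each fit. The NAC call ended without a filter (0.0612), and the defensin call ended with median-of-ratios scaling (0.0840), the stricter filter (0.0618), organelle genes removed (0.0528) and limma-voom (0.102). With 1 library left out, adjusted p ran from 0.0315 to 0.591 for evening-phased clock genes, 0.00233 to 0.644 for cold, 4.33e-06 to 0.188 for abscisic acid, 0.000990 to 0.0514 for salicylic acid, 0.00517 to 0.165 for heat and handling, and 0.00632 to 0.298 for stomatal genes. Of the families, it ran from 0.00677 to 0.642 for organellar ribosomal proteins, 5.72e-07 to 0.791 for histones, 0.0149 to 0.801 for cytochromes P450, 0.0430 to 0.537 for peroxidases, 0.000189 to 0.0787 for WRKY factors, 0.00534 to 0.791 for cyclins and 0.0132 to 0.0666 for defensins. Direction turned, uncalled in either fit, for chlorophyll breakdown (0.305 to 0.716), chlorophyll synthesis (0.0972 to 0.906), starch (0.165 to 0.802), root (0.230 to 0.721), glutathione S-transferases (0.369 to 0.932), MYB factors (0.111 to 0.875) and glucosinolate genes (0.0605 to 0.866), and for peroxidases without Col-0 replicate 2 (0.166) and without lux-6 replicate 2 (0.537). DESeq2 was not run because the values are not counts, and scaling by library size alone is the deposited scaling.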

Other observations

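The tests of counting noise, harvest time, seed material, handling and a sustained jasmonate response were chosen after their results, or values close to them, had been seen. Among families taken from product names, ERF/DREB factors were called higher in lux-6 with a median log2 fold change of 0.39 over 81 members (camera adjusted p = 6.48e-05; adjusted p = 0.672 with an estimated correlation). ESE3 (AT5G25190) rose by 2.60, and 15 members passed upwards and 1 downwards when adjusted over the list alone. SAUR proteins, induced early by auxin, had a median of 0.50 (camera adjusted p = 0.000722; adjusted p = 0.672 with an estimated correlation), with SAUR24 (AT5G18080) at 1.80. The medians of ERF/DREB factors and SAUR proteins were 0.22 and 0.34 without Col-0 replicate 2. Xyloglucan endotransglucosylases/hydrolases, which remodel cell walls, had 0.55 (camera adjusted p = 0.000990), B-box factors 0.56 (0.00167), NAC factors 0.33 (0.00140) and WRKY factors 0.14 (0.00715), each at adjusted p = 0.672 with an estimated correlation. These medians were 0.21, 0.26, 0.09 and 0.11 without Col-0 replicate 2. WRKY33 (AT2G38470) rose from 19.7 ± 4.07 to 182 ± 35.9 FPKM (SD, n = 2). Ribosomal proteins not named as organellar were called lower with a median of -0.45 over 330 members (camera adjusted p = 1.58e-20; adjusted p = 0.672 with an estimated correlation). Col-0 replicate 2 lay above replicate 1 by 0.61 in that family, and without it the median was -0.15. Product names alone made the split, so the family termed organellar holds only proteins named so. The other may hold organellar proteins as well, and the results of the 2 families cannot be set against each other. Histones (camera adjusted p = 0.00167), heat shock proteins (0.00493), cyclins (0.0243) and defensins (0.0424) were called lower with medians of -0.31, -0.16, -0.13 and -0.37, each at adjusted p = 0.672 with an estimated correlation. They were -0.04, -0.17, -0.05 and -0.33 without Col-0 replicate 2. Of the defensins 2 passed upwards and 2 downwards over the list alone, and LCR67, a related gene that rose, has a product name without that word and is not in the family. The calls of histones and cyclins ended without Col-0 replicate 2, at adjusted p = 0.791 for both, that of defensins without Col-0 replicate 2 (0.0666), and that of WRKY factors without Col-0 replicate 1 (0.0787). The remaining families were not called, namely organellar ribosomal proteins (0.0686), cytochromes P450 (0.125), bHLH (0.179), aquaporins (0.346), MYB (0.346), expansins (0.448), peroxidases (0.587), glutathione S-transferases (0.590) and glucosinolate genes (0.590), by camera adjusted p. Organellar ribosomal proteins were called without Col-0 replicate 1 (0.00677) and without lux-6 replicate 1 (0.0216), and cytochromes P450 (0.0149) and peroxidases (0.0430) without Col-0 replicate 1.

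Col-0 replicate 2 lay apart from the other libraries. Removal of organelle genes left the r of the Col-0 libraries at 0.923, from 0.909, and removal of a running median over gene length left the SD of their difference at 0.690, from 0.704, both beyond the bounds set for those explanations. Counting noise is argued against as well, because chi-square per gene was 4.29 times that of the lux-6 pair. Another harvest time cannot be told apart from other differences between these samples. Morning-phased genes lay -0.32 ± 0.0836 (SE) from the median of all genes, and evening-phased genes -0.01. Evening-phased genes went both ways from Col-0 replicate 1 to 2, with PRR7 from 22.0 to 12.4 FPKM and LUX from 57.0 to 73.9. Their median therefore does not show that they stayed level. The SE is over genes of the morning-phased list, which are not independent replicates. It gives no precision for a difference between single libraries. No biological explanation was tested, nor was a wrong label or another preparation, which stay open.

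Beside the fixed seed storage markers, called higher in lux-6 by camera but not with an estimated correlation (adjusted p = 0.563), more seed transcripts were read. In a wider list written after the fixed markers were seen, 19 of 20 genes were tested. Of those, 100% were higher in both lux-6 libraries than in both Col-0 libraries, with a median of 2.72. The 5 that passed over all genes are among the 57 genes called above, so they are not further evidence. Of the 19 tested genes 18 were lower in Col-0 replicate 2 than in replicate 1, and without Col-0 replicate 2 the median was 2.08. The rises were unequal, with log2 fold changes from 1.89 to 6.95. Against Col-0 replicate 1, SESA3 went from 0.473 to 180 and 138 FPKM in lux-6, and EM1 (AT3G51810) from 31.2 to 95.7 and 106. Seed material in the lux-6 tissue may account for the higher values, but whether it alone gives such unequal rises was not tested. Activity of embryonic regulators may also account for them. The bound set beforehand for these was met by FUS3 (AT3G26790) at 1.92 and 1.89 FPKM in lux-6. FUS3 also stood at 1.32 FPKM in Col-0 replicate 1 and did not pass the test, and LEC1 and LEC2 were listed at 0 in both lux-6 libraries, so both explanations stay open, and so does the genotype itself, as untested.

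In a list of 19 rapid touch and wound transcripts written after the results were seen, which was not tested against other genes, 4 passed over all genes, namely CML38, TCH3 (AT2G41100), WRKY33 and RRTF1 (AT4G34410), which had been called before it was written. RRTF1 rests on 0 and 1 fragments in Col-0 and did not pass with limma-voom (adjusted p = 0.106). The 19 were higher in both lux-6 libraries than in both Col-0 libraries, with a median of 2.25. In Col-0 replicate 2, 15 were lower than in replicate 1, and without Col-0 replicate 2 the median was 1.78. Handling at harvest could raise them, and cannot be told apart from genotype because the lux-6 tissue was collected as its own samples. A sustained jasmonate response is a candidate explanation, but 8 slower jasmonate markers had a median of 0.56 with all 4 libraries and -0.04 without Col-0 replicate 2, and none passed, so the test decides nothing, and the effect of the lux-6 genotype stays open as untested.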
